A study of Mus musculus with 50 samples.

How the data were processed

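Poly(A) RNA of colon from 50 BALB/c mice was sequenced, 1 library per mouse, in 5 groups of 10 mice. The groups were sham mice, TNBS mice given vehicle, and TNBS mice given A1007 at 10, 30 or 90 mpk, a unit printed here as the labels give it. TNBS is trinitrobenzene sulfonic acid, a hapten used to provoke colitis in mice. A1007 is described in the series as an agonist of the aryl hydrocarbon receptor (AhR), a transcription factor switched on by small ligands. The labels give colon as the tissue, which the series text narrows to its distal part, and place all mice in 1 batch.

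The authors deposited raw read counts per gene and mouse in 1 table of 56691 genes. The same table held deposited FPKM values (fragments per kilobase of exon, scaled to library size), an exon length per gene, coordinates on GRCm39 and gene symbols. Per the submitters' processing notes the work used cutadapt 1.9.1, HISAT2 2.2.1, HTSeq 0.6.1, DESeq2 and the mouse build GRCm39. The role and order of these tools, the strand setting of the counting and the treatment of reads that fit several genes are not given in the sources used here. The authors' FPKM values were checked against the counts, the exon lengths and the library totals. Of the values with at least 500 counts, 99.997% lay within 1% of the recomputed ones. The deposited exon length served only for this check. Symbols were missing for 2639 genes, and 959 genes shared a symbol with another gene and were kept apart by their Ensembl identifiers. Values of close paralogs (the Reg, Mptx, Try and Ugt1a families, and Hspa1a with Hspa1b) are uncertain to the extent that they share reads.

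Library totals ran from 16031757 to 20391034 counts in sham, 15324404 to 18916591 counts in vehicle, 14497205 to 19149227 counts in 10 mpk, 15494095 to 18362878 counts in 30 mpk and 14373337 to 20446967 counts in 90 mpk mice. On simulated counts with the means and library sizes of sham and vehicle mice, edgeR recovered 61% of genes changed 1.5-fold and 78% of genes changed 2-fold, with 3 false calls among 17928 genes. The same check recovered 58% and 86.5% for the 10 mpk comparison, 54.5% and 87.5% for 30 mpk, 62.6% and 82% for 90 mpk, and 66% and 87% for the dose trend. False calls numbered 2, 10 and 8 at 10, 30 and 90 mpk and 12 for the trend. The simulated genes varied independently of each other, with the same spread in every group and no outlying libraries. These numbers of false calls therefore hold for such counts and do not measure those in the real data.

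Everything below the table was computed in R 4.3.3. The plan made before the data were examined took FPKM as the deposited unit, tested with limma, and named edgeR's quasi-likelihood test in its place if the table held counts. Counts were found, so edgeR 4.0.16 was used throughout (glmQLFit and glmQLFTest with robust estimation, TMM scaling, genes kept by filterByExpr with a count minimum of 10). This left 17928 genes for testing. TNBS vehicle and each dose were compared with sham on the 20 mice of the pair of groups. The dose comparisons, the differences between doses and a trend over dose steps 0, 1, 2 and 3 were fitted on the 40 TNBS mice. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and intervals are 95% intervals of the log2 fold change. Every adjusted p of a gene below is from this edgeR test unless another tool is named. Levels are given as mean FPKM ± SD over 10 mice.

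Of 439 genes in 30 lists fixed before the data were examined, 438 were in the table. The lists cover AhR targets and other xenobiotic genes, inflammatory mediators, immune, epithelial, stromal, neural and vascular cell types, extracellular matrix, proliferation, handling stress, the mitochondrial genome and neighbouring tissues. Each was tested with camera (limma 3.58.1, preset correlation 0.01, at least 5 tested members) and adjusted over the lists. The same test with an estimated correlation, and fry, were run beside it. Camera compares a list with all other genes, whereas fry asks whether the list's own genes move on balance one way. Members that rose or fell are counted over all genes tested, and also as adjusted over the list alone where that count differs. Lists of clock, pancreatic acinar, pancreatic islet and distal Hox genes were added after the data had been seen.

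The named genes followed a rule fixed in the same plan. It took all tested AhR targets, the 8 largest rises and the 8 largest falls among called genes with a mean FPKM of at least 2 in either group, and up to 4 called members of each list with the smallest p, or up to 2 with the highest FPKM where none was called. Predicted genes, pseudogenes and immunoglobulin or receptor segments were left out of the largest changes. Genes named for the differences between doses, for the comparisons of doses with sham and in the closing part were chosen after their values were seen.

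Alternatives fixed before the data were examined were limma on log2 FPKM with a pseudocount of 0.1, 0.5 or 1, quantile normalization, array quality weights, no filter, a stricter filter (FPKM of at least 2 in at least 10 mice), DESeq2 1.42.0, DESeq2 size factors in edgeR, all 50 mice in 1 fit, only the 2 groups compared, a rank-sum test, a replicate block, and an added limit on the fold change. The trend was also fitted on dose in mpk and on the 3 dose groups alone. Leaving out single libraries or pairs of libraries was added after the data had been seen. Replicate numbers recur in every group and were not taken as pairs.

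To compare each dose with the disease change, genes called between vehicle and sham were counted by their direction under the dose. Both contrasts use the vehicle mice, which alone gives opposite signs. The correlation was therefore also computed for simulated groups with neither a TNBS change nor a dose effect, and with 5 vehicle mice in each contrast and none shared. Scores per mouse are means of log2 CPM (counts scaled to library size) over a list; the clock score is the activating list minus the repressing and output list.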

Results

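TNBS vehicle mice had higher levels of genes of inflammation and of the extracellular matrix than sham mice. S100a9, an alarmin of neutrophils, averaged 748.5 ± 1260 FPKM in 10 vehicle mice against 0.747 ± 0.637 in 10 sham mice (log2 fold change 10.10, SE 1.43, adjusted p = 4.16e-05). Il1b, an inflammatory cytokine, averaged 54.16 ± 77.9 against 1.119 ± 0.409 FPKM, and Col4a1, a collagen of basement membranes, 106.9 ± 34 against 25.55 ± 3.05 FPKM. Slc26a3, the chloride and bicarbonate exchanger of surface colonocytes, was lower, at 55.27 ± 19.8 against 181.3 ± 39.2 FPKM. Of 17928 genes tested, 5677 changed, 3290 of them higher and 2387 lower in vehicle mice, and 1203 changed at least 2-fold, 989 higher and 214 lower. The share of higher calls was 58%, and 41% with quantile normalization.

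Among the immune lists, those of myeloid cells, cytokines, chemokines and mast cells passed the camera test at the preset correlation. All 10 tested neutrophil markers rose (median log2 fold change 6.22), among them Cxcr2, a chemokine receptor, at 7.59 and Mmp9, a gelatinase, at 4.45 (camera adjusted p = 2.95e-09, adjusted p = 0.181 with an estimated correlation). All 18 monocyte and macrophage markers rose as well (median 1.95), with Csf1r, the receptor of macrophage growth factor, at 1.18, the complement gene C1qb at 1.53 and the mannose receptor Mrc1 at 1.56 (camera adjusted p = 6.86e-23, 0.0352 with an estimated correlation). Of the inflammatory cytokines 11 of 13 rose, Il6 by 8.37 and Il11 by 5.48 on the log2 scale (adjusted p = 3.98e-05, and adjusted p = 0.182 with an estimated correlation). Of the chemokines 14 of 22 rose, among them the neutrophil attractant Cxcl5 at 8.50 and the monocyte attractant Ccl8 at 2.79 (adjusted p = 3.98e-05, and adjusted p = 0.189 with an estimated correlation). Mast cell and eosinophil markers split into 7 that rose, with the mast cell protease Mcpt2 at 4.46, and 2 that fell (adjusted p = 0.0212, and adjusted p = 0.393 with an estimated correlation).

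Matrix genes rose as well. Collagens rose in 15 of 16 cases (median 1.76), with the fibrillar collagen gene Col5a2 at 2.14 (camera adjusted p = 1.1e-38, 0.0049 with an estimated correlation). Fibrosis mediators and matrix proteins rose in 21 of 24 cases, with the collagen cross-linking enzyme Lox at 5.13 and fibronectin, Fn1, at 2.22 (adjusted p = 3.58e-23, 0.0352 with an estimated correlation). Of the matrix metalloproteinases and inhibitors 13 of 15 rose and 1 fell, Mmp10 at 5.09 and the membrane-bound Mmp14 at 1.39 (adjusted p = 1.07e-11, 0.0313 with an estimated correlation). Endothelial genes rose in 11 of 13 cases, and in 12 adjusted over the list alone, a count given from here on only where it differs (adjusted p = 1.96e-07, and adjusted p = 0.181 with an estimated correlation). Proliferation genes rose in 11 of 18 cases, 12 adjusted over the list alone (adjusted p = 0.00401, and adjusted p = 0.604 with an estimated correlation; the call is lost with fry).

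Epithelial genes moved in both directions. Of the absorptive colonocyte genes 9 of 20 fell and 0 rose in edgeR, with the membrane carbonic anhydrase Car4 at -1.50, its cytosolic relative Car2 at -0.93 and the proton pump gene Atp12a at -2.28 (camera adjusted p = 3.22e-06, and adjusted p = 0.131 with an estimated correlation). The xenobiotic and NRF2 list split into 2 that rose, heme oxygenase Hmox1 at 2.52 among them, and 7 that fell, 9 adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.182 with an estimated correlation; the call is lost with quantile normalization and with all 50 mice in 1 fit). Squamous epithelium genes rose in 4 of 7 cases and adjusted over the list alone 1 fell, with the keratin gene Krt13 at 7.21 (adjusted p = 0.0264, and adjusted p = 0.369 with an estimated correlation; the call is lost with each pseudocount, with weights and with quantile normalization). Genes of the epithelial antimicrobial list included Lcn2, which binds bacterial siderophores, at 8.03 and the acute-phase gene Saa3 at 6.33, and Cldn8, a claudin of tight junctions, rose by 1.38. Axin2, a target of Wnt signalling, fell by 0.82.

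Of the 8 tested AhR targets 1 rose and 2 fell. Cyp1b1, a cytochrome P450 enzyme, rose by 4.55, and by 3.79 without vehicle replicate 6; it had 8.69, 14.51 and 4.93 FPKM in vehicle replicates 5, 6 and 9 and 0.16 to 1.45 FPKM in the other 7. Ugt1a6a, a glucuronosyltransferase, fell by 0.99. The list median was -0.33, its mean 0.26, and the camera test pointed down without passing (adjusted p = 0.31). Ahr itself rose by 0.19. Cyp1a1, the enzyme most often read as a measure of AhR activity, had 0.242 ± 0.202 FPKM in vehicle mice and 0.338 ± 0.15 in sham mice (log2 fold change -0.45, interval -1.35 to 0.44, adjusted p = 0.432).

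**Figure D1:**
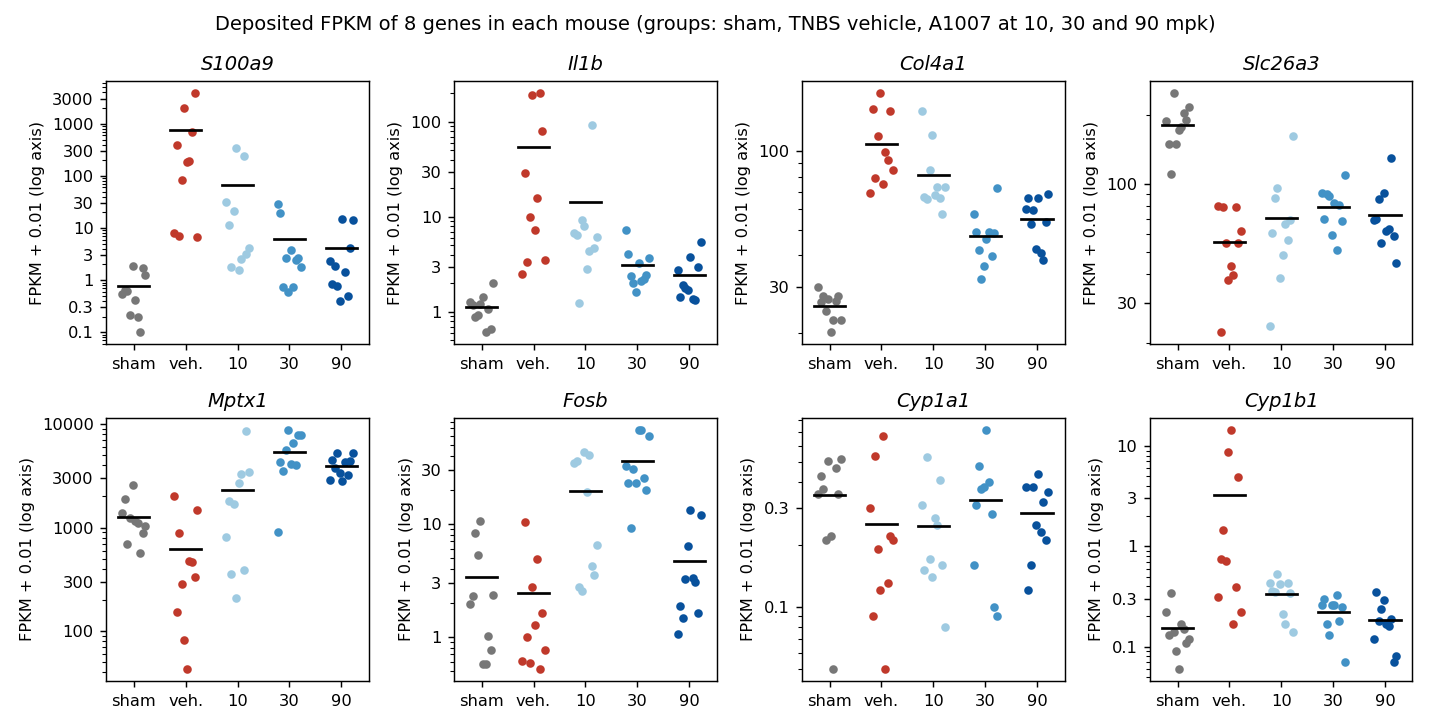
FPKM plus 0.01 of 8 genes on a log axis, 1 point per mouse and 10 mice per group, for sham, TNBS vehicle and A1007 at 10, 30 and 90 mpk. Bars mark group means.

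Beside these lists, genes of the circadian clock differed between vehicle and sham mice, and genes of the pancreas were high in 4 of 10 vehicle mice. Ciart, Dbp and Hlf, which belong to the repressing and output arm of the clock, fell by 2.56, 2.41 and 1.91 in vehicle mice. Arntl, of the activating arm, had 4.21 ± 1.25 against 1.12 ± 0.144 FPKM. In all, 10 of 10 genes of the repressing and output list fell, and 3 of 5 genes of the activating list rose. The activating list is not one of activators alone. It also holds Nfil3 (2.79) and Cry1 (-0.14, adjusted p = 0.335), which code for repressors. Among pancreatic acinar genes Ctrb1 rose by 12.06, Cpa1 by 12.12 and Cela3b by 11.93, and without vehicle replicate 6 by 8.04 to 8.68. All 3 code for digestive enzymes or their precursors. Vehicle replicate 6 held 60100 CPM of 16 acinar genes, against at most 12.3 CPM in sham mice. All 16 acinar genes and 2 of 2 tested islet genes rose, 16 and 1 without that library. Of the islet genes, Ppy was also higher at 30 mpk than in sham mice, by 1.61 (adjusted p = 2.04e-06). In A1007 30 replicate 10 it had 25.3 CPM with acinar CPM of 8.26, within the sham range, so Ppy alone does not mark pancreas here. Calls of Ctrb1, Cpa1 and Cela3b are lost with limma on log2 FPKM and with the rank-sum test.

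**Figure D2:**
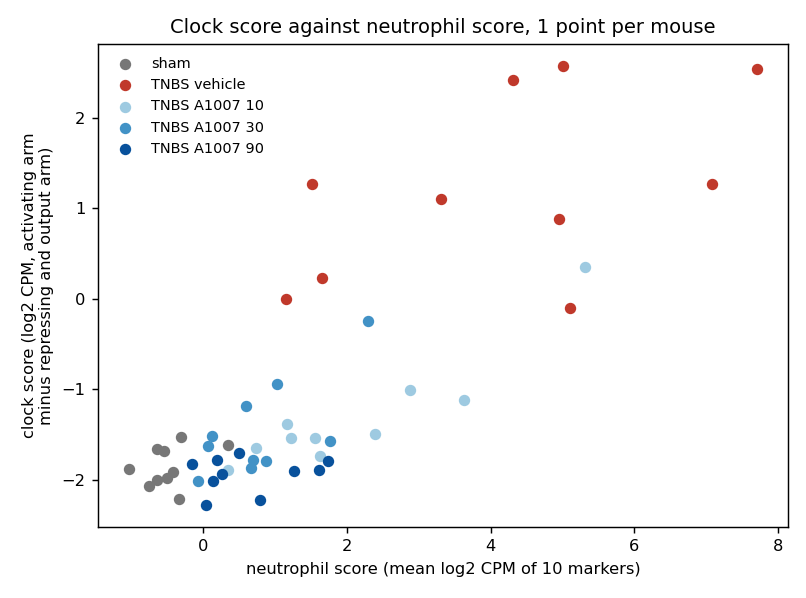
Clock score against neutrophil score, 1 point per mouse, coloured by group. Each score is a mean of log2 CPM over its list. The clock score is the activating list minus the repressing and output list. Nfil3 and Cry1, in the activating list, code for repressors.

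At 10 mpk, A1007 mice had lower inflammatory genes and higher immediate early genes than TNBS vehicle mice. Il6 averaged 0.446 ± 0.565 FPKM in 10 dosed mice and 6.469 ± 11 in 10 vehicle mice (log2 fold change -3.96, SE 0.81, adjusted p = 0.0056). Fosb, an early response transcription factor, averaged 19.41 ± 17.5 against 2.438 ± 3.11 FPKM (2.98, SE 0.64, adjusted p = 0.00687). In all, 1038 genes changed, 490 higher and 548 lower, and 233 by at least 2-fold. The share of higher calls was 47.2%, 62.2% with quantile normalization and 60% with a pseudocount of 0.5. These SEs and adjusted p use a spread shared by all TNBS mice, and the groups compared here varied more than the other dose groups. Between libraries of a group the median chi-square per degree of freedom was 97.7 in vehicle and 78.2 in 10 mpk mice. It was 27.1 at 30 mpk and 20.5 at 90 mpk. The SEs and adjusted p at 10 mpk can therefore be too small. The count depends on the test and on single mice. In 5 of 100 splits of the 20 mice compared, the real one included, at least as many genes were called, so chance is not excluded for it. All genes named for 10 mpk lose their calls with the rank-sum test, and all but Jun and Hlf with only the 2 groups compared. The count was 8 with only the 2 groups compared, 0 with the rank-sum test (2445 genes at an unadjusted p under 0.05) and 1749 with all 50 mice in 1 fit. Leaving out 1 library gave 512 (A1007 10 replicate 7), 516 (vehicle replicate 5), 559 (A1007 10 replicate 6), 595 (A1007 10 replicate 9), 662 (A1007 10 replicate 2), 675 (vehicle replicate 2), 685 (vehicle replicate 7) or 2453 (A1007 10 replicate 5).

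Of the neutrophil markers 5 of 10 fell, 10 adjusted over the list alone, S100a8 by 3.81 and Mmp9 by 1.58 on the log2 scale (camera adjusted p = 4.13e-06, and adjusted p = 0.461 with an estimated correlation). Macrophage markers fell in 7 of 18 cases, 13 adjusted over the list alone, the scavenger receptor Msr1 by 1.29 (adjusted p = 2.01e-07, and adjusted p = 0.461 with an estimated correlation). Inflammatory cytokines fell in 3 of 13 cases, 8 adjusted over the list alone (adjusted p = 0.00308, and adjusted p = 0.461 with an estimated correlation). Fibrosis mediators fell in 8 of 24 cases, 10 adjusted over the list alone, with the metalloproteinase inhibitor Timp1 at -2.54 (adjusted p = 0.00013, and adjusted p = 0.461 with an estimated correlation). The epithelial antimicrobial list had 4 of 17 members that fell, and adjusted over the list alone 8 fell and 2 rose, with Lcn2 at -4.26 and Saa3 at -3.84 (adjusted p = 0.0195, and adjusted p = 0.461 with an estimated correlation). Ccl2, a monocyte attractant, fell by 2.39 and Cldn8 by 1.17. Il6, Ccl2, S100a8, Lcn2 and Timp1 also lose their calls with limma on log2 FPKM, and S100a8 and Timp1 without a filter, with the replicate block and without the 2 mice low in Xist. Mmp9, Msr1 and Saa3 lose theirs with weights, and S100a8 also without A1007 10 replicates 3 and 8. The cytokine and fibrosis lists lose their calls with weights and with fry, and the antimicrobial list with fry, without vehicle replicate 6 and without A1007 10 replicates 3 and 8.

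Of the immediate early and heat shock genes 8 of 13 rose, 9 adjusted over the list alone, Atf3 by 2.26, Jun by 1.18 and the chaperone gene Hspa1a by 1.52 (camera adjusted p = 7.49e-11, and adjusted p = 0.42 with an estimated correlation). Smooth muscle genes rose in 3 of 12 cases, 4 adjusted over the list alone, with the myosin light chain gene Myl9 at 0.58 (adjusted p = 1.2e-05, and adjusted p = 0.461 with an estimated correlation), and neuron and glia genes in 3 of 13 cases, 5 adjusted over the list alone, with the glial gene S100b at 1.01 (adjusted p = 0.0137, and adjusted p = 0.461 with an estimated correlation). Mptx1, a pentraxin of the intestinal epithelium, rose by 1.92, a call also lost with each pseudocount, with weights, with the replicate block and without a filter. Dbp and Hlf rose by 2.15 and 1.66. The pancreatic genes Reg2, Pnliprp1 and Ctrc fell by 9.03, 6.49 and 5.41. These 3 calls are lost with limma on log2 FPKM, at least those of Reg2 and Pnliprp1 with the replicate block, and those of Pnliprp1 and Ctrc also without vehicle replicate 6. Ctrc loses its call with DESeq2 and without a filter as well, and Myl9 without a filter and with weights. The smooth muscle list and the neuron and glia list lose their calls with fry.

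**Figure D3:**
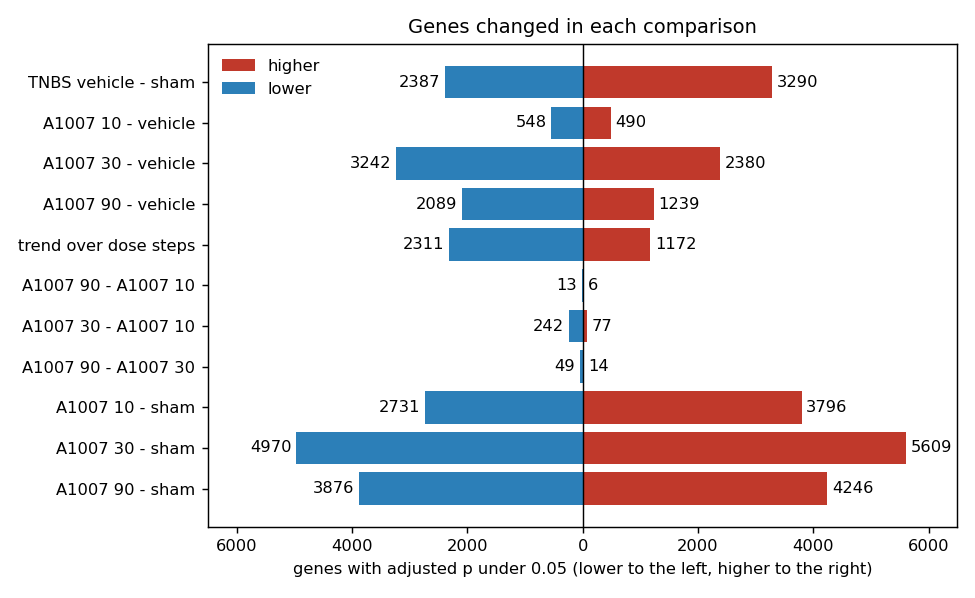
Number of genes changed in each comparison at an adjusted p under 0.05, lower to the left and higher to the right. The comparisons are those of vehicle and each dose with sham, of each dose with vehicle, between doses, and the trend.

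At 30 mpk, 5622 genes changed against TNBS vehicle, 2380 higher and 3242 lower, and 865 by at least 2-fold. S100a9 averaged 6.281 ± 9.53 FPKM in 10 dosed mice against 748.5 ± 1260 in 10 vehicle mice (log2 fold change -6.99, SE 1.32, adjusted p = 0.000186). Mptx1 averaged 5367 ± 2450 against 622.3 ± 654 FPKM (3.15, SE 0.58, adjusted p = 0.000132), and Fosb 35.92 ± 21.3 against 2.438 ± 3.11 FPKM (3.92, SE 0.66, adjusted p = 5.57e-05). Of the calls 42.3% were higher, and 54.6% with quantile normalization.

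Neutrophil markers fell in 9 of 10 cases at 30 mpk, 10 adjusted over the list alone (median -4.25, camera adjusted p = 1.61e-06, and adjusted p = 0.313 with an estimated correlation), and macrophage markers in 15 of 18, 16 adjusted over the list alone, with Mrc1 at -1.18 and Csf1r at -0.82 (adjusted p = 4.68e-12, and adjusted p = 0.0975 with an estimated correlation). Inflammatory cytokines fell in 9 of 13 cases, Il6 by 5.29 and Il11 by 4.90 (adjusted p = 0.000833, and adjusted p = 0.372 with an estimated correlation). Among single genes Ccl2 fell by 3.05, Cxcl5 by 5.26, Lcn2 by 6.46, Saa3 by 6.71 and Hmox1 by 1.85. Collagens fell in 15 of 16 cases (median -1.12), with Col5a1 at -1.23 (adjusted p = 1.11e-14, and adjusted p = 0.0975 with an estimated correlation). Fibrosis mediators fell in 20 of 24 cases, 21 adjusted over the list alone, with Pdgfra, a receptor of fibroblasts, at -0.99 (adjusted p = 1.25e-13, and adjusted p = 0.0975 with an estimated correlation). Matrix metalloproteinases and inhibitors fell in 11 of 15 cases, Mmp2 by 0.98 (adjusted p = 1.13e-06, and adjusted p = 0.0975 with an estimated correlation). Proliferation genes fell in 10 of 18 cases, 15 adjusted over the list alone (adjusted p = 0.000111, and adjusted p = 0.616 with an estimated correlation). The calls of Lcn2 and Hmox1 are lost with the rank-sum test.

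Immediate early and heat shock genes rose in 11 of 13 cases at 30 mpk (median 1.77), Atf3 by 3.19, Jun by 1.77 and Hspa1a by 2.18 (adjusted p = 1.25e-13, and adjusted p = 0.0975 with an estimated correlation). Smooth muscle genes rose in 6 of 12 cases, Myl9 by 0.73 (adjusted p = 0.000193, and adjusted p = 0.499 with an estimated correlation). Among epithelial genes Ang4, an antimicrobial ribonuclease, rose by 2.76, Car2 by 0.90 and Cldn23 by 0.81, whereas Cldn8 fell by 1.17. Insl5, a hormone of colonic enteroendocrine cells, rose as well (adjusted p = 0.000573). Of 4 distal Hox genes, whose levels vary along the length of the colon, Hoxd13 was also higher, at 0.99 (adjusted p = 0.0423). Cd79b, of the B cell receptor, rose by 1.12 and Gstm1, a glutathione transferase, by 0.78.

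**Figure D4:**
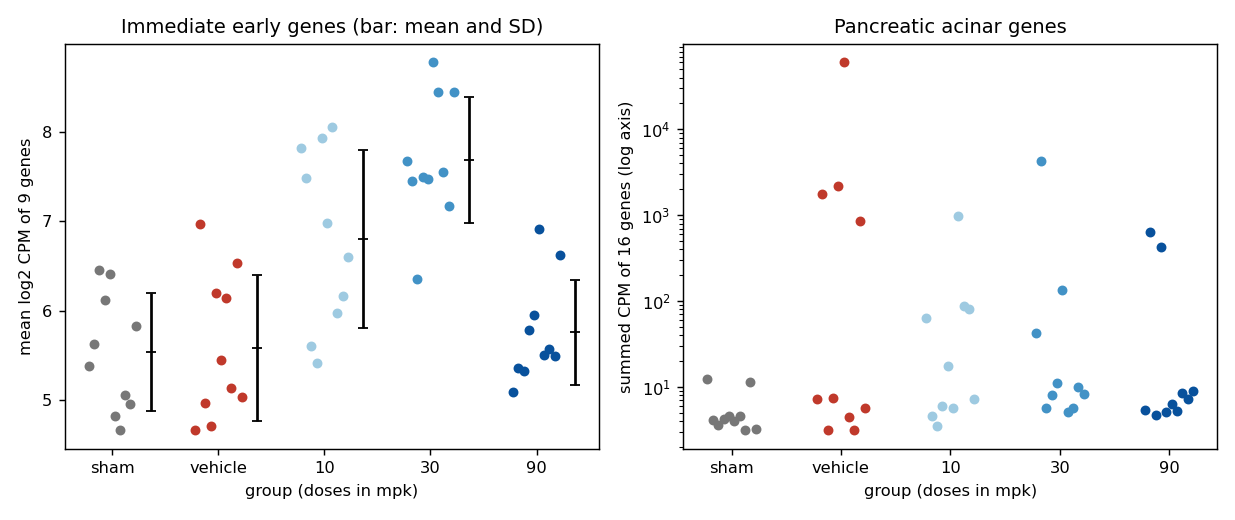
Left, immediate early score of 9 genes per mouse and group, with mean and SD. Right, summed CPM of 16 pancreatic acinar genes per mouse on a log axis.

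At 90 mpk, 3328 genes changed against TNBS vehicle, 1239 higher and 2089 lower, and 699 by at least 2-fold. Il1b averaged 2.452 ± 1.34 FPKM in 10 dosed mice against 54.16 ± 77.9 in 10 vehicle mice (log2 fold change -4.49, SE 0.80, adjusted p = 0.000153). Col4a1 averaged 54.76 ± 11.2 against 106.9 ± 34 FPKM (-1.01, SE 0.17, adjusted p = 7.13e-05), and Mptx1 3966 ± 908 against 622.3 ± 654 FPKM (2.65, SE 0.57, adjusted p = 0.00102). Higher calls made up 37.2%, and 56.9% with quantile normalization and 55.4% with a pseudocount of 0.5.

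All 10 neutrophil markers fell at 90 mpk (median -4.36), S100a8 by 8.53 and Mmp9 by 2.68 (camera adjusted p = 1.51e-09, and adjusted p = 0.118 with an estimated correlation). Macrophage markers fell in 17 of 18 cases, Mrc1 by 1.27 (adjusted p = 8.93e-17, and adjusted p = 0.0816 with an estimated correlation), inflammatory cytokines in 11 of 13, Il6 by 6.30 and Il11 by 5.06 (adjusted p = 2.96e-06, and adjusted p = 0.118 with an estimated correlation), and chemokines in 11 of 22, Ccl2 by 3.33, while adjusted over the list alone 1 chemokine also rose (adjusted p = 0.00866, and adjusted p = 0.407 with an estimated correlation). Collagens fell in 14 of 16 cases, 15 adjusted over the list alone (median -0.98, adjusted p = 4.47e-15, and adjusted p = 0.0816 with an estimated correlation). Fibrosis mediators fell in 18 of 24 cases, Lox by 2.76 (adjusted p = 4.47e-15, and adjusted p = 0.0816 with an estimated correlation). Matrix metalloproteinases and inhibitors fell in 10 of 15 cases, Mmp10 by 4.03 (adjusted p = 2.98e-07, and adjusted p = 0.0816 with an estimated correlation). Proliferation genes fell in 14 of 18 cases, 17 adjusted over the list alone, with Mki67, a marker of cycling cells, at -0.73 (adjusted p = 2.94e-07, and adjusted p = 0.349 with an estimated correlation).

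Smooth muscle genes rose in 5 of 12 cases at 90 mpk, 6 adjusted over the list alone, with Lmod1 at 0.74 (adjusted p = 3.62e-06, and adjusted p = 0.319 with an estimated correlation). Squamous epithelium genes fell in 5 of 7 cases (adjusted p = 0.0146, and adjusted p = 0.319 with an estimated correlation; the call is lost with weights and without a filter). The antimicrobial list had 2 members that rose and 9 that fell, 3 and 11 adjusted over the list alone, Lcn2 by 6.64 and Saa3 by 6.52 (adjusted p = 0.0371, and adjusted p = 0.349 with an estimated correlation), and the call of the list is lost with weights and without vehicle replicate 6, and that of Lcn2 with the rank-sum test. Itln1, a lectin that binds microbial sugars, rose by 2.31, Ang4 by 2.59, Car2 by 0.58 and Gstm1 by 0.58. Dbp rose by 2.44 and Ciart by 2.08. Of the immediate early and heat shock genes 0 of 13 passed in edgeR, and Jun had a log2 fold change of 0.59 (adjusted p = 0.0648), which passes in 6 of the alternatives, DESeq2 among them.

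**Figure D5:**
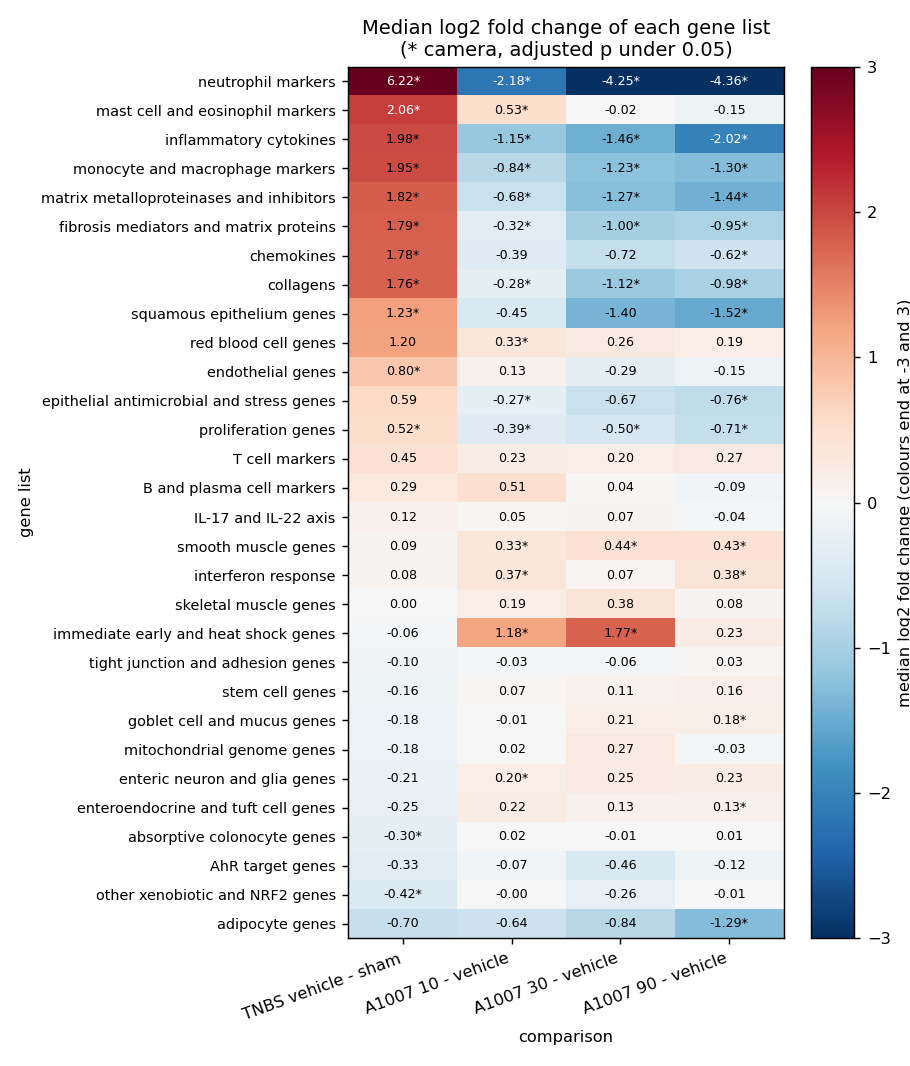
Median log2 fold change of the 30 lists in vehicle against sham and in each dose against vehicle; colours end at 3 in either direction. Asterisks mark lists with a camera adjusted p under 0.05 at the preset correlation.

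AhR targets were not higher under any dose in edgeR. Against vehicle, 1, 3 and 2 of 8 targets fell at 10, 30 and 90 mpk and 0 rose, with 2 and 4 falling at 10 and 30 mpk adjusted over the list alone (camera adjusted p = 0.293, 0.257 and 0.299). Cyp1b1 fell by 3.37, 3.98 and 4.29, and without vehicle replicate 6 by 2.60, 3.22 and 3.52, and at 90 mpk it stood at 0.26 against sham (adjusted p = 0.501). Vehicle replicates 5, 6 and 9, which held the high Cyp1b1 values, also had 2160, 60100 and 866 CPM of acinar genes. Their neutrophil scores were 7.08, 4.95 and 7.71. Vehicle replicate 2 had 1760 CPM of acinar genes and 0.73 FPKM of Cyp1b1. How much of the fall remains without replicates 5, 6 and 9 together was not tested. Tiparp, an ADP-ribosyltransferase induced by AhR ligands, fell by 0.56 at 30 mpk and by 0.60 at 90 mpk. Ugt1a6a fell by 0.99 at 30 mpk, a call lost with a pseudocount of 0.1 and without a filter. Cyp1a1 averaged 0.237 ± 0.139, 0.319 ± 0.19 and 0.275 ± 0.106 FPKM at the 3 doses, with log2 fold changes against vehicle of -0.04 (interval -0.85 to 0.77, adjusted p = 0.968), 0.42 (-0.38 to 1.21, adjusted p = 0.431) and 0.14 (-0.66 to 0.94, adjusted p = 0.844). Cyp1a1 had 2 to 35 counts per mouse, so its intervals are wide.

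Over the dose steps, 3483 genes followed a trend, 1172 rising and 2311 falling. Per step Mmp9 fell by 0.91 (SE 0.11, adjusted p = 1.1e-06), Mrc1 by 0.45, Col5a1 by 0.41 and Cyp1b1 by 1.48, and Car2 rose by 0.23 and Mptx1 by 0.96. Macrophage markers fell in 17 of 18 cases, collagens in 15 of 16, fibrosis mediators in 20 of 24 (21 adjusted over the list alone) and matrix metalloproteinases and inhibitors in 10 of 15, each with an adjusted p of 0.0386 with an estimated correlation. The share of rising genes was 33.6%, 56.4% with quantile normalization and 51.6% with a pseudocount of 0.5. With dose in mpk the number of genes with a dose trend was 1349, and over the 3 dose groups alone 300. The calls of Car2 and Mptx1 are lost in both, and that of Cyp1b1 over the 3 doses.

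Between 10 and 30 mpk 319 genes differed, 77 higher and 242 lower at 30 mpk. Col1a1 and Col3a1, of fibrillar collagen, were lower at 30 mpk by log2 fold changes of -1.09 (SE 0.27, adjusted p = 0.0256) and -0.81 (SE 0.21, adjusted p = 0.037). Collagens fell in 14 of 16 cases from 10 to 30 mpk, 16 adjusted over the list alone (adjusted p = 1.13e-23, 0.0497 with an estimated correlation). Higher at 30 mpk were 24.1% of the calls, and 43.8% with quantile normalization. The count was 99 without A1007 10 replicates 3 and 8, 125 without a filter, 3552 with weights, 869 with all 50 mice in 1 fit, 796 with DESeq2 and 832 without the 2 mice low in Xist. Col1a1 loses its call without a filter, and Col3a1 loses it there, with the rank-sum test and without A1007 10 replicates 3 and 8. Leaving out 1 library gave 158 (A1007 30 replicate 5), 161 (A1007 10 replicate 8), 164 (A1007 10 replicate 1), 171 (A1007 30 replicate 4), 173 (A1007 10 replicate 4), 174 (A1007 30 replicate 8), 590 (vehicle replicate 5), 595 (A1007 10 replicate 7), 600 (A1007 10 replicate 6), 717 (vehicle replicate 9) or 1401 (A1007 10 replicate 9).

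Between 30 and 90 mpk 63 genes differed, 14 higher and 49 lower at 90 mpk. Immediate early genes were among them: Atf3 fell by 3.61 (SE 0.51, adjusted p = 0.000116), Fosb by 2.99 and Jun by 1.18, and 10 of 13 list members fell, 12 adjusted over the list alone (adjusted p = 5.91e-25, 0.0146 with an estimated correlation). Higher at 90 mpk were 22.2% of these, and 46.2% with a pseudocount of 0.5. The count depends strongly on the test: it was 3064 with only the 2 groups compared, 2753 with the rank-sum test, 5244 with weights and 625 with the replicate block. It was 437 with all 50 mice in 1 fit, 234 with DESeq2, 107 without A1007 10 replicates 3 and 8 and 104 without the 2 mice low in Xist. The 63 uses a spread shared by all 40 TNBS mice, and vehicle and 10 mpk libraries varied more. Between libraries of a group the median chi-square per degree of freedom was 97.7 in vehicle and 78.2 in 10 mpk mice. It was 27.1 at 30 mpk and 20.5 at 90 mpk. Leaving out 1 library gave 28 (A1007 30 replicate 6), 31 (A1007 90 replicate 3), 33 (A1007 30 replicate 10), 35 (A1007 90 replicate 1), 38 (A1007 90 replicate 5), 39 (A1007 90 replicate 2 or 7), 218 (A1007 10 replicate 9) or 610 (vehicle replicate 9).

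Between 10 and 90 mpk 19 genes differed, 6 higher and 13 lower at 90 mpk. Col3a1 had a log2 fold change of -0.83 (SE 0.21, adjusted p = 0.0867), which passes with DESeq2 and with all 50 mice in 1 fit. Collagens fell in 1 of 16 cases, 16 adjusted over the list alone (adjusted p = 4.09e-23, and adjusted p = 0.0551 with an estimated correlation). Of the differing genes 31.6% were higher, 55.6% with quantile normalization and 58.3% with a pseudocount of 0.5. The count was 90 with only the 2 groups compared, 48 with the rank-sum test, 64 with weights, 102 with all 50 mice in 1 fit, 184 with DESeq2 and 82 without A1007 10 replicates 3 and 8, and 10 to 12 with pseudocounts of 0.1 and 0.5, without a filter and without the 2 mice low in Xist. Leaving out 1 library gave 9 (A1007 10 replicate 1), 10 (A1007 90 replicate 7), 11 (A1007 90 replicate 4) or 12 (A1007 30 replicates 1 and 7, A1007 90 replicates 1, 5 and 10).

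Genes changed by TNBS were compared with those changed by each dose. Of the 5677 genes, 547 (9.64%), 1944 (34.2%) and 1941 (34.2%) changed in the opposite direction at 10, 30 and 90 mpk, and 23, 173 and 8 in the same direction. Calls drawn independently would give 166, 912 and 548 opposite and 163, 868 and 506 in the same direction. Genes higher under TNBS and lower under the dose numbered 369, 1391 and 1386. Across genes the fold changes correlated at -0.67, -0.63 and -0.80. The shared vehicle mice contribute to this. On log CPM the correlations were -0.52, -0.53 and -0.73, with covariances of -0.0983, -0.148 and -0.192. Simulated groups with neither a TNBS change nor a dose effect gave correlations of -0.59, -0.67 and -0.65. Their covariances were -0.0271, -0.0292 and -0.0277. The simulated correlations hold no TNBS change, so they do not show what the shared mice give beside one. With 5 vehicle mice in each contrast and none shared the median correlations over 100 draws were -0.37 (-0.62 to 0.05), -0.44 (-0.62 to -0.09) and -0.58 (-0.73 to -0.34). Calls over 10 such draws gave median opposite counts of 261 (32 to 457), 1295 (1140 to 1530) and 1266 (860 to 1551), with up to 61, 1101 and 50 genes in the same direction. The opposite count at 10 mpk was 4 with only the 2 groups compared and 0 with the rank-sum test.

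Against sham, the dosed mice differed in 6527, 10579 and 8122 genes at 10, 30 and 90 mpk, the last 4399 with all 50 mice in 1 fit. These counts exceed the 5677 of vehicle mice, but each comes from its own fit of 20 mice and depends on the spread of its groups. Changes of at least 2-fold numbered 1026, 1153 and 560, against 1203 for vehicle mice. Slc26a3 was lower by log2 fold changes of -1.35, -1.16 and -1.33 and Car4 by -1.26, -1.21 and -1.19, while Col4a1 was higher at 1.67, 0.92 and 1.07 and Mrc1 at 1.10, 0.38 and 0.29. Absorptive colonocyte genes fell in 10, 11 and 15 of 20 cases (camera adjusted p = 9.3e-06, 0.00159 and 1.25e-08; adjusted p = 0.0801, 0.391 and 0.155 with an estimated correlation). Collagens rose in 16, 11 and 13 of 16 cases, 12 at 30 mpk adjusted over the list alone (adjusted p = 0.0208, 0.513 and 0.155 with an estimated correlation). Insl5 was above sham at 30 and 90 mpk, by 1.84 and 1.17, and Mptx1 by 2.13 and 1.63, with 0.90 at 10 mpk (adjusted p = 0.188). Among 4 distal Hox genes, Hoxb13 and Hoxd13 were higher than in sham mice at 30 mpk, by 0.62 (adjusted p = 0.000881) and 0.68 (adjusted p = 0.00825), and Hoxa13 was lower at 10 mpk, at -0.34 (adjusted p = 0.0496). S100a9 was still higher at 90 mpk (2.44, adjusted p = 0.0103), a call lost with a pseudocount of 1, quantile normalization, all 50 mice in 1 fit and the rank-sum test, and Mrc1 at 90 mpk loses its call without a filter, with all 50 mice and with the rank-sum test. Dbp at 90 mpk stood at 0.03 (adjusted p = 0.77). The share of higher calls at 10 mpk was 58.2%, and 42.9% with quantile normalization.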

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

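The tests of time of day, of severity of inflammation and of a general TNBS effect, carry-over and rising dose, and the splits of only the 2 groups compared, were chosen only after the results had been seen; those of pancreas RNA and handling were written down before their values were computed.

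Clock genes set TNBS vehicle mice apart. The clock score averaged 1.21 ± 1.02 in vehicle mice, -1.86 ± 0.223 in sham mice and -1.3, -1.46 and -1.94 at 10, 30 and 90 mpk. In a fit with a common slope over 40 TNBS mice, vehicle mice stood 1.92 (SE 0.26) above dosed mice at the same neutrophil score. Vehicle replicates 1, 3 and 10, with neutrophil scores of 1.15, 1.51 and 1.65, had clock scores of -0.01, 1.27 and 0.23. Dosed mice with neutrophil scores between 1.15 and 1.65 had -1.91 to -1.39. A1007 10 replicate 5, at 5.32, had 0.35, within the vehicle range. The neutrophil score alone thus did not account for the difference. An imperfect measure of severity can leave such an offset, so severity as the whole cause is not excluded. As a part it stays open, with 0.29 (SE 0.06) per unit of neutrophil score. Within groups r was 0.35 in sham, 0.52 in vehicle, 0.91 in 10 mpk, 0.68 in 30 mpk and 0.18 in 90 mpk mice. At 10 mpk its adjusted p was 0.00645, and the rank correlation was 0.78 (adjusted p = 0.0802). Collection at another time of day may be a cause: 10 of 10 vehicle mice lay above all sham mice, and the labels give no time, so group and time cannot be separated. An effect of A1007 on the clock remains a biological candidate that this design cannot part from time.

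Pancreatic genes were high in single libraries. In vehicle replicate 6 acinar genes made up 6.01% of counts, and Iapp and Ppy, of islets, reached 139 CPM together against at most 6.43 in sham mice, which RNA of pancreas in the library could explain. Iapp alone had 102 CPM there and the insulin gene Ins2 139 CPM, against at most 0.883 and 0 in sham mice. Carry-over from that library as the only source is excluded, because 13 of 13 other libraries above the sham range had other proportions of acinar genes (chi-square per degree of freedom 14.7 to 986, set against counting error only, as carried-over reads would keep the proportions); Pnlip per 100 counts of Ctrb1 ran from 4.15 to 69.2 against 8.53, and Prss1 had 312 counts in A1007 30 replicate 2 against 2. An effect of TNBS in every inflamed mouse is excluded for these genes, because 6 vehicle mice with a raised neutrophil score had acinar CPM within the sham range. An effect limited to severe inflammation was not tested. The vehicle mice above the sham range, replicates 2, 5, 6 and 9, had neutrophil scores of 5.01, 7.08, 4.95 and 7.71. Replicate 8 had 5.1 with acinar CPM within the sham range, and the other vehicle mice had 1.15 to 4.31. Without vehicle replicate 6, 16 of 16 acinar genes still rose against sham, and 0 fell against vehicle at any dose in edgeR, where 5, 3 and 15 fell with it.

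Immediate early genes were high at 10 and 30 mpk, with scores of 6.8 and 7.69 against 5.58 in vehicle and 5.76 at 90 mpk. An effect that rises with dose is excluded as the whole cause, because 10 of 13 members were lower at 90 than at 30 mpk. As a part it stays open, because handling that differed between the groups could hide it. Severity of inflammation is excluded as the whole cause, because 11 members were higher at 30 mpk than in vehicle mice, whose neutrophil markers were higher; within vehicle mice the score followed the neutrophil score with r = 0.74 (p = 0.0165, adjusted p = 0.108). Handling of the tissue may be a cause and stays open, as the labels give no handling times. Within 30 mpk the heat shock score followed the immediate early score with r = 0.7 (p = 0.0266, adjusted p = 0.108, rank correlation 0.59). The value was 0.64 (p = 0.0461, adjusted p = 0.115, rank correlation 0.43) within vehicle mice, 0.29 within sham mice, 0.28 (p = 0.416) within 10 mpk and -0.07 within 90 mpk. Without the 2 mice of each group farthest from its median immediate early score, r was 0.62 within 30 mpk and 0.22 within vehicle mice. It was then 0.64 within sham mice, -0.14 within 10 mpk and -0.1 within 90 mpk.

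Single mice stood far from the other 9 of their group, by a gap to the nearest mouse, as a part of the group's range, above the 95% limit of Dixon's test for 10 values. Gap and range were taken on log2 FPKM with a pseudocount of 0.5 for genes, on log2 CPM for acinar genes and Xist, and on the scores themselves. Of 251 tested values 25 (9.96%) lay beyond Dixon's limit, where chance puts about 1 in 20. The gap was 0.518 for Cpa1 in sham replicate 9, 0.611 for Cela3b in sham replicate 1, 0.477 for Cxcr2 in sham replicate 10 and 0.473 for Mmp10 in sham replicate 2. Cpa1, Cela3b and Cxcr2 were near the floor there, at 0.23, 0.2 and 0.1 FPKM. In sham replicate 5 the gap was 0.577 for Ccl8, 0.585 for Mcpt2 and 0.474 for the neutrophil score. In vehicle replicate 5 it was 0.571 for Tiparp and 0.482 for Insl5. At 10 mpk it was 0.565 for Ccl2 in replicate 3, 0.666 for Ctrc in replicate 7, 0.478 for Col3a1, 0.512 for Col1a1 and 0.478 for Car4 in replicate 1, and 0.688 for Dbp, 0.505 for Hlf and 0.604 for the clock score in replicate 5. At 30 mpk it was 0.598 for Mptx1, 0.625 for Ang4 and 0.514 for Myl9 in replicate 1, 0.526 for Cd79b in replicate 3, 0.511 for acinar CPM in replicate 2 and 0.518 for the distal Hox score in replicate 10. Xist, a transcript of the inactive X chromosome, was 0.935 CPM in A1007 10 replicate 6 (gap 0.878; others 329 to 741 CPM) and 1.79 CPM in A1007 30 replicate 1 (gap 0.94; all others of the group far higher, up to 526 CPM). Counts of Y-linked genes were 0 in both libraries, and the low Xist was not explained.

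The effects of the doses differed from each other by a direct test in 19 genes (90 against 10 mpk), 319 genes (30 against 10 mpk) and 63 genes (90 against 30 mpk). Among 100 splits of the 40 TNBS mice, the real one included, 3, 2 and 4 gave at least as many genes, with 1174, 560 and 1550 as the highest others. Among 100 splits of only the 20 mice compared it was 2, 1 and 1, with 28, 95 and 0 as the highest others, so chance is excluded at 0.05 for each, without adjustment over the 11 counts tested. Splits of the 40 mice that call many times the real 19 and 63 genes also deal vehicle mice into the dose groups. Their counts can therefore hold the difference between vehicle and dosed mice, and the splits of only the 20 mice compared gave no such counts. For the comparisons with vehicle, only the real split of the 40 mice reached its count, 1038 genes at 10 mpk (highest other 981), 5622 at 30 mpk (797) and 3328 at 90 mpk (1995), as for the trend with 3483 genes (2194). Among splits of only the 20 mice compared, 5 of 100 reached 1038 genes at 10 mpk (highest other 4681), so chance is not excluded there. The 4681 genes point to a structure of the samples, whose cause was not tested. At 30 and 90 mpk only the real split reached its count (3804 and 957). Against sham only the real split did so as well, with 5677 genes for vehicle (34), 6527 at 10 mpk (391), 10579 at 30 mpk (7664) and 8122 at 90 mpk (0). Chance is excluded at 0.05 for the counts against sham, at 30 and 90 mpk against vehicle and for the trend. This too is without adjustment over the 11 counts tested. The splits for the trend deal vehicle mice over the dose steps. They therefore cannot part a trend among the doses from a difference between vehicle and dosed mice.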

How the results depend on the processing

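Leaving out libraries was chosen only after the data had been seen. Within 1.5 times the reported count lay 14 of 15 alternatives for vehicle against sham, 5 of 16, 15 of 16 and 15 of 16 for 10, 30 and 90 mpk against vehicle, 13 of 16 for the trend, 5 of 16, 9 of 16 and 7 of 16 for 90 against 10, 30 against 10 and 90 against 30 mpk, and 14, 14 and 13 of 15 for the doses against sham. With an added limit of an absolute log2 fold change of 1 the counts were 1203 for vehicle against sham, 233, 865 and 699 for the doses against vehicle, 115 for the trend, 6 (90 against 10), 34 (30 against 10), 23 (90 against 30) and 1026, 1153 and 560 against sham. At 10 mpk against vehicle the count was 549, 565 and 541 with pseudocounts of 0.1, 0.5 and 1, 529 without a filter, 682 with quantile normalization, 1749 with all 50 mice, 8 with only the 2 groups, 516 with weights, 0 with the rank-sum test and 615 without the 2 mice low in Xist. The genes with a dose trend numbered 1349 on mpk and 300 on 3 doses. For 90 against 10 mpk the counts were 10 and 12 with pseudocounts of 0.1 and 0.5, 12 without a filter, 102 with all 50 mice, 90 with only the 2 groups, 64 with weights, 48 with the rank-sum test, 184 with DESeq2, 82 without A1007 10 replicates 3 and 8 and 11 without the low-Xist mice. For 30 against 10 mpk they were 125 without a filter, 869 with all 50 mice, 3552 with weights, 796 with DESeq2, 99 without replicates 3 and 8 and 832 without the low-Xist mice. For 90 against 30 mpk they were 437 with all 50 mice, 3064 with only the 2 groups, 5244 with weights, 2753 with the rank-sum test, 234 with DESeq2, 107 without replicates 3 and 8 and 104 without the low-Xist mice. At 90 mpk against sham all 50 mice gave 4399. The cause of these shifts was not tested.

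Lists called numbered 13, 14, 9 and 15 for vehicle against sham and the doses against vehicle. They became 4, 0, 0 and 0 with an estimated correlation, 20 for vehicle against sham without a filter, and 9 with the stricter filter and 3 with fry at 10 mpk. Without vehicle replicate 6 they were 12 at 10 mpk and 12 at 90 mpk. Opposite genes at 10 mpk numbered 276, 283 and 273 with the pseudocounts, 301 without a filter, 346 with quantile normalization, 903 with all 50 mice, 4 with only the 2 groups, 210 with weights, 0 with the rank-sum test, 178 with the limit on fold change and 261 with no vehicle mouse shared. At 30 mpk they were 498 with that limit and 1295 with none shared, and at 90 mpk 531 and 1266. Pnliprp1 at 10 mpk turned to 0.05 with weights (adjusted p = 0.987; 0.00449 to 1 over its alternatives). Of 151 called pairs of gene and comparison examined singly, 88 kept their call in every alternative and 63 lost it at least once; 4 of 18 others gained one (Actg2 for vehicle against sham, Jun at 90 mpk against vehicle, Col3a1 for 90 against 10 mpk and Cyp1a1 at 10 mpk against sham).

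Leaving out 1 library at a time gave 4771 to 6108 genes for vehicle against sham, 512 to 2453, 4562 to 6895 and 2634 to 3768 for the doses against vehicle, 2711 to 3866 for the trend, 9 to 28 for 90 against 10, 158 to 1401 for 30 against 10 and 28 to 610 for 90 against 30 mpk. Over 100 pairs of libraries with the same replicate number, the correlation of their deviations from the group means ran from -0.28 to 0.5. In 12 of the 100 pairs the library of the first group had its best match in the other group under its own number. With the replicate block 625 genes differed between 30 and 90 mpk, 4384 between vehicle and sham, and 936, 6032 and 3231 for the doses against vehicle.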

Other observations

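The tests in this part were run on lists fixed beforehand, and the library values were picked only after they had been seen. Between vehicle and sham, lists that did not pass as a whole still held single changes. T cell markers rose in 2 of 14 cases (camera adjusted p = 0.144), B and plasma cell markers in 3 of 13 (0.209) and skeletal muscle genes in 2 of 5 (0.91; median 0.00, mean 0.19, test direction down). Goblet cell genes fell in 3 of 14 cases (0.119) and mitochondrial genome genes in 2 of 13 (0.105). Enteroendocrine and tuft cell genes had 2 that rose and 6 that fell of 12 (0.0883), stem cell genes 2 and 5 of 12 (0.119), tight junction genes 2 and 7 of 19 (0.172; median -0.10, mean 0.03), and antimicrobial genes 7 and 1 of 17 (0.145). The IL-17 and IL-22 list had 3 that rose and 1 that fell of 7, 3 and 3 adjusted over the list alone (0.593; median 0.12, mean -0.15). Neuron and glia genes had 3 and 2 of 13 (0.651), immediate early genes 2 and 3 of 13 (0.31), with Hspa1a at -1.76, and red blood cell genes 1 and 0 of 5, 0 adjusted over the list alone (0.79). In edgeR 0 of 20 interferon genes (0.933), 0 of 12 smooth muscle genes (0.784; Actg2 0.56, adjusted p = 0.0914) and 0 of 8 adipocyte genes (0.459) passed.

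Further lists passed camera under the doses. At 10 mpk interferon genes pointed up with 0 of 20 passing in edgeR (camera adjusted p = 0.00574, and adjusted p = 0.609 with an estimated correlation), and at 90 mpk 2 of 20 rose (0.000706, and adjusted p = 0.478 with an estimated correlation). At 90 mpk enteroendocrine and tuft cell genes rose in 3 of 12 cases, 4 adjusted over the list alone (0.049, and adjusted p = 0.349 with an estimated correlation; the call is lost with DESeq2 size factors, the stricter filter, all 50 mice in 1 fit and without vehicle replicate 6). At 10 mpk proliferation genes pointed down with 0 of 18 passing in edgeR (5.12e-06, and adjusted p = 0.461 with an estimated correlation), collagens down with 0 of 16 (0.0385, and adjusted p = 0.698 with an estimated correlation), and mast cell markers up with 0 of 9, where adjusted over the list alone 1 rose (0.0146, and adjusted p = 0.461 with an estimated correlation). Red blood cell genes pointed up with 0 of 5 (0.0137, and adjusted p = 0.461 with an estimated correlation), and matrix metalloproteinases and inhibitors fell in 2 of 15 cases, while adjusted over the list alone 4 fell and 1 rose (0.0214, and adjusted p = 0.461 with an estimated correlation). At 90 mpk goblet cell genes had 2 that rose and 1 that fell of 14, 5 and 2 adjusted over the list alone (0.0371, and adjusted p = 0.407 with an estimated correlation), and adipocyte genes 1 that fell of 8, 0 adjusted over the list alone (0.0322, and adjusted p = 0.553 with an estimated correlation). Of these calls, at 10 mpk all are lost with fry, that of red blood cell genes without vehicle replicate 6, those of collagens, metalloproteinases and interferon genes with weights, those of collagens and metalloproteinases without A1007 10 replicates 3 and 8, those of collagens and mast cell markers without the 2 mice low in Xist, and those of collagens, metalloproteinases and mast cell markers with the stricter filter. At 90 mpk interferon genes lose it with weights and with fry, goblet cell genes with weights, and adipocyte genes with fry, all 50 mice in 1 fit and without vehicle replicate 6. T cell markers, of which none passed against vehicle in edgeR, rose against sham in 8, 10 and 11 of 14 cases at 10, 30 and 90 mpk, 10 at 10 mpk adjusted over the list alone (adjusted p = 0.496, 0.697 and 0.439 with an estimated correlation), and mast cell and eosinophil markers in 7 of 9 at each dose, with 2 that fell at 30 mpk (adjusted p = 0.261, 0.391 and 0.155 with an estimated correlation).

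Some libraries differ in ways left unexplained. A1007 10 replicates 3 and 8 had 3.39 and 1.57 CPM of Hoxd13 and 15.8 and 8.74 CPM of Hoxb13, genes of the posterior body axis. A1007 10 replicate 9 had a mitochondrial share of 2.611%.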
